A study of Rattus norvegicus and Homo sapiens with 6 samples.

How the data were processed

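RNA from primary human and rat Schwann cells at passage 2 was extracted with a Qiagen RNeasy kit and depleted of ribosomal RNA with an Epicentre kit, per the labels. The deposited values are whole-number read counts per gene, not normalized, in 1 table of all 6 libraries and in 1 file per library, and the 2 forms differed in 0 cells. The submitters' processing notes name CASAVA 1.4, Trim Galore, STAR and HTSeq and the build hg38, with no versions for the last 3 tools. The genome build and annotation used for the rat reads, the strand setting of the counting and the rule that paired human with rat genes are not given in the sources used here. Each of the 16483 rows pairs a human symbol with 1 rat symbol, and 15570 pairs have the same symbol apart from case. HTSeq leaves reads that overlap more than 1 gene uncounted in its usual mode, so genes that share exons may lose counts, and the mode used is not given. No correction for gene length was made, because exon lengths of the rat annotation were not used here, so a gene with longer exons in one species gains counts there.

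From the table, 4 sex-linked rows were removed and 12343 genes were kept by filterByExpr of edgeR 4.0.16, leaving 4136 untested, of which 491 had no count. Library sizes were scaled by TMM, a quasi-likelihood model was fitted with robust dispersion (glmQLFit and glmQLFTest, R 4.3.3), and two-sided p-values were adjusted by the Benjamini-Hochberg method at 0.05. Log2 fold changes are human minus rat. Levels are counts per 1000000 (CPM) with the SD over 3 libraries. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 25 lists with at least 5 tested members, and again with an estimated correlation, under which 0 lists were called. The fry test, which asks whether the genes of a list move on balance one way and does not compare the list with other genes, called 24 lists. Human gene positions, exon overlaps and named pseudogenes came from GENCODE 29 on GRCh38, in which 15959 of the human symbols (96.8%) were found. A gene counts as sharing exons when at least 50% of its exonic bases lie in another gene on either strand.

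The sample groups and replicate numbers came from the library titles. The lists, the tests of genes and of lists, the rule for named genes and all alternatives except 1 were fixed before the data were examined. The tests of ubiquitous genes, leukocyte markers, class II loci and fibroblast markers were chosen afterwards. The rule took the 12 genes per direction with the largest fold change among genes with adjusted p below 0.05, at least 10 counts in each library, at least 10 CPM in the higher species and no overlap between species. To these it added the 6 most abundant genes per direction with at most 3 counts in each library of the other species. It also took 4 members per list by level and 2 by fold, and SOX10, S100B, NGFR, ERBB3, MKI67 and THY1. Some genes that the rule selects are not reported here. Other list members and the families of the closing section were named after their values were seen. Counts of ribosomal protein genes and of other genes with near-identical copies are uncertain where reads match several loci.

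Total counts ran from 22850015 to 31535841 per library. On simulated counts for the 12343 genes with 200 changed genes, the test recovered 70% of genes changed 1.25-fold, 92% of those changed 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 6.25% of calls were false. Most genes were unchanged in the simulation, whereas 11287 were called in the data, so these rates do not describe the comparison of species. The alternatives were RLE, upper-quartile and housekeeping scaling, DESeq2 1.42.0, limma-voom, other count filters, a test against a 2-fold change, a replicate block, the per-library files, leaving out ribosomal protein, histone and mitochondrial genes, and leaving out each library. Leaving out genes with shared human exons or named pseudogenes was added after seeing the data. Housekeeping scaling moved the log2 fold changes of all genes by a median of -0.19.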

Results

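Gene expression was measured by RNA sequencing in primary Schwann cells, the glial cells that ensheath and myelinate peripheral axons, grown from human and from rat tissue. Total RNA was taken at passage 2 and depleted of ribosomal RNA. There were 3 human and 3 rat libraries, and the comparison asks how the cultured cells of the 2 species differ. Total counts over the paired genes were 29752061, 28037085 and 22850015 in rat libraries 1 to 3, and 31204573, 26098256 and 31535841 in human libraries 1 to 3. A floor of 3 counts corresponded to between 0.0951 and 0.131 counts per 1000000 (CPM) in these libraries, for counting error only. The labels do not say whether the libraries came from separate donors, animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. Species was also confounded with genome, gene annotation, gene length and mappability, so each difference is one in counts as obtained for each species. Any feature of the donors, animals, cultures or library runs that differed between the 2 groups cannot be told apart from species either.

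Transcripts of the Schwann cell lineage were abundant in both species. S100B, a calcium-binding glial marker (GRCh38 chromosome 21, 46598962 to 46605208), was at 3105 ± 40.8 CPM in human and 1012 ± 41.8 CPM in rat (SD, n = 3), a log2 fold change of 1.62 (SE 0.05, edgeR adjusted p = 1.41e-13). NGFR, the low-affinity neurotrophin receptor (chromosome 17, 49495293 to 49515017), was also higher in human, at 1883 ± 34.2 against 917 ± 47.4 CPM. SOX10, the transcription factor that specifies the lineage (chromosome 22, 37970686 to 37987422), was lower in human, at 135 ± 5.10 against 318 ± 17.0 CPM, with a log2 fold change of -1.23 (SE 0.05). ERBB3, a neuregulin receptor (chromosome 12, 56076799 to 56103505), was lower in human by a small margin, at 490 ± 7.95 against 628 ± 31.8 CPM. Of the 20 Schwann lineage genes tested, 12 were higher in human and 8 in rat, and the list did not differ from other genes (camera adjusted p = 0.845). ITGA6, a laminin receptor subunit, reached 8649 CPM in human and 1137 CPM in rat, whereas SCN7A, a sodium channel gene, was at 0.471 CPM in human and 1506 CPM in rat. FABP7, a fatty acid binding protein of immature glia, was at 85.4 CPM in human with 0 to 1 counts per rat library.

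Markers of other cell types differed in level between the cultures. Leukocyte markers were scarce in both species, the most abundant being CD14 at 1.23 CPM in human and CD68 at 1.38 CPM in rat. Fibroblast markers had a median of 9.12 CPM in human and 0.136 CPM in rat over the 21 genes in the table, while the Schwann lineage list had medians of 441 and 751 CPM. THY1, a surface protein used to detect fibroblasts (chromosome 11, 119417378 to 119424985), was at 12.3 ± 1.04 CPM in human, with 0, 1 and 1 counts in the rat libraries. The neurofilament genes NEFL and NEFM were abundant in rat, at 3841 ± 461 and 848 ± 133 CPM, against 62.8 ± 0.625 and 40.9 ± 2.48 CPM in human, while NEFH was at 4.20 CPM in rat and 0.776 CPM in human. The 14 neuron markers in the table, these 3 included, had medians of 0.431 CPM in human and 0.0923 CPM in rat. Of them, 5 reached 10 CPM in human and 3 in rat. MOXD1, on the perineurial list, was at 1766 CPM in human and 77.1 CPM in rat. PTCH1 and ITGB4, on the same list, were higher in rat.

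**Figure D1:**
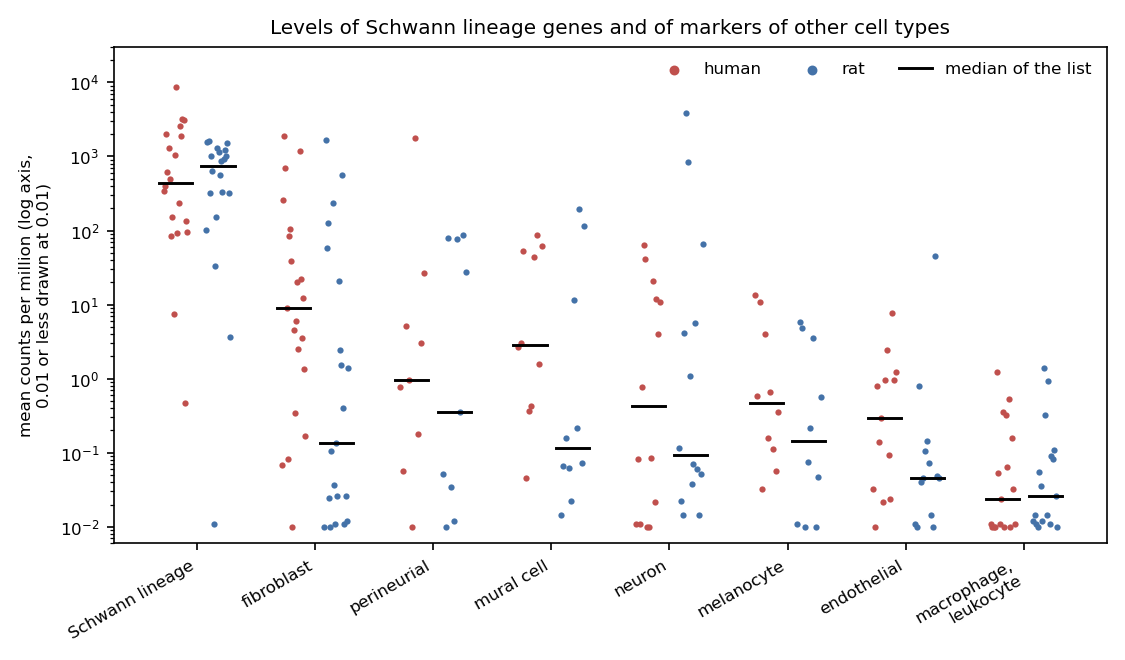
Mean CPM (log axis) of each gene on the Schwann lineage list and on 7 lists of markers of other cell types, with human and rat means of 3 libraries as points and list medians as bars. The leukocyte points all lie at or below 1.38 CPM, while the Schwann lineage medians are 441 CPM in human and 751 CPM in rat.

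Libraries of one species resembled each other far more than those of the other species. Across the genes tested, mean log2 expression in human and rat had a Spearman correlation of 0.689 and a Pearson correlation of 0.616. Pairs of single libraries were compared on log2 of CPM plus 1. Their Pearson correlations were between 0.997 and 0.999 within a species and between 0.681 and 0.686 across species. Genes are not independent replicates, so these values are descriptive. The biological coefficient of variation was 2.42% in human and 7.25% in rat. Rat library 2 stood apart from the other rat libraries, and without it the rat value was 2.64%. In that library RPL41, HSPG2 and ACTB lay below the mean of rat libraries 1 and 3 by log2 differences of -0.59, -0.53 and -0.41, and PNN and HSP90AA1 lay above it by 0.74 and 0.60. The counts of every pair of libraries differed by more than counting noise (chi-square per gene at least 1.77 where counting noise alone gives 1), as those of technical repeats also can, so this does not show that the libraries are separate cultures. Each was counted as labelled.

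Among genes with at least 10 counts in each of the 6 libraries, those furthest above rat in the human cells included QKI, THBS1, SPP1 and AGPAT9. QKI, an RNA-binding protein that regulates splicing in glia (chromosome 6, 163414000 to 163578596), was at 2632 ± 60.5 CPM in human and 5.25 ± 0.517 CPM in rat, a log2 fold change of 8.98 (SE 0.07, adjusted p = 2.44e-18). THBS1, a secreted matrix glycoprotein (chromosome 15), was at 1085 ± 22.3 against 1.29 ± 0.435 CPM, and SPP1, the matrix protein osteopontin (chromosome 4), at 181 ± 2.48 against 0.661 ± 0.0567 CPM. The largest fold change among these genes was that of AGPAT9, a glycerolipid acyltransferase gene, at 10.17 (SE 0.11). KATNAL1, KCNE4, BVES, TFPI2, TPM2, DDR2 and ATP2B4 were also among the 12 genes selected in this direction, with log2 fold changes between 7.89 and 9.70.

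Under the same limit of 10 counts, those furthest above human in the rat cells included RELN, DCLK1, S100A4 and APITD1. RELN, the secreted glycoprotein reelin (chromosome 7, 103471784 to 103989516), was at 1923 ± 124 CPM in rat and 2.29 ± 0.602 CPM in human, a log2 fold change of -9.71 (SE 0.12, adjusted p = 1.49e-15). DCLK1, a microtubule-associated kinase (chromosome 13), was at 1399 ± 48.3 against 5.19 ± 0.122 CPM, and S100A4, a calcium-binding protein (chromosome 1), at 1478 ± 163 against 7.94 ± 0.763 CPM. APITD1 had the largest change among them, at -9.77 (SE 0.09). TTYH1, GBP5, AKAP2, CYP51A1, CRABP2, TSPAN7, PDE3B and APC2 completed the 12, with values between -8.98 and -7.62. In human, 85.8% of the exonic bases of AKAP2 and 83.2% of those of CYP51A1 also belong to another annotated gene. The symbols AGPAT9 and APITD1 had no match in the human annotation used, so their overlaps are not known.

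Of 12343 genes tested, 11287 (91.4%) differed between species, 5752 being higher in human and 5535 in rat. A difference of at least 2-fold was found for 7135 genes, 3833 higher in human and 3302 in rat, and the median absolute log2 fold change was 1.26. Which species had more of the higher genes depended on the scaling, with 5526 higher in human and 5818 in rat under upper-quartile scaling, and 5165 and 6050 (3512 and 3744 at 2-fold) under housekeeping scaling. When the test was made against a 2-fold change instead of no change, 6604 genes passed. The spread between libraries was small beside these differences, and 1056 genes were not called.

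**Figure D2:**
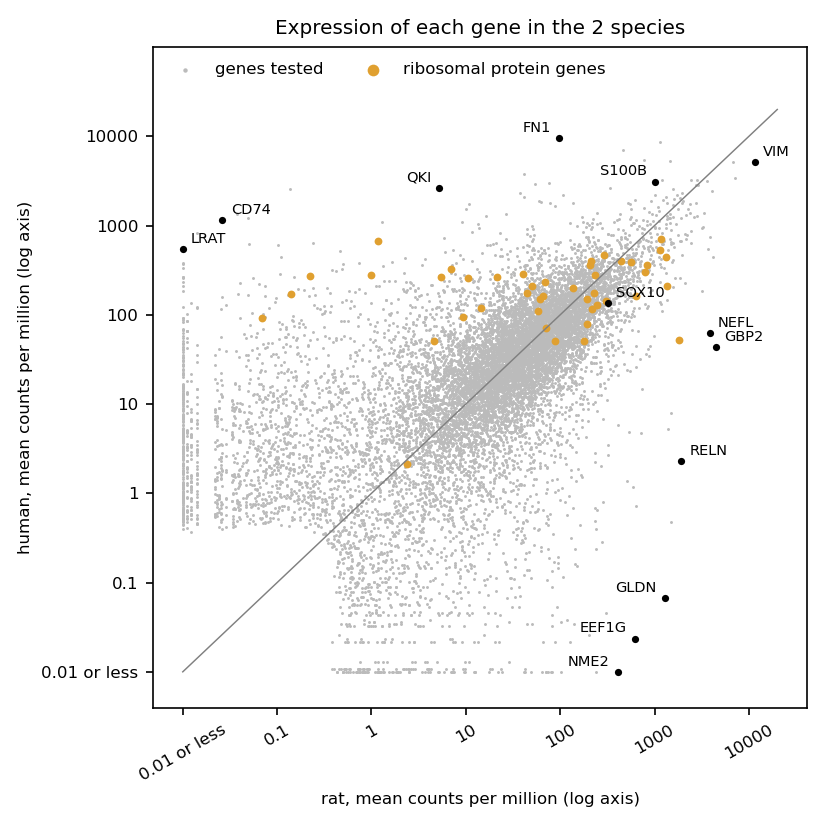
Mean CPM of each of the 12343 genes tested, rat on the horizontal and human on the vertical log axis, with the diagonal marking equal values and means of 0.01 or less drawn at 0.01. Ribosomal protein genes lie on both sides of the diagonal, from RPL7 (52.4 CPM in human, 1801 CPM in rat) to RPS9 (91.5 and 0.0690 CPM).

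Some genes were abundant in one species and almost uncounted in the other, with at most 3 counts per library. In human these were led by COL8A1, a short-chain collagen (chromosome 3, 1342 ± 37.9 CPM, 1 count in each rat library), A2M, a protease inhibitor (chromosome 12, 1220 ± 7.53 CPM), CD74, the MHC class II invariant chain (chromosome 5, 150401637 to 150412929, 1154 ± 15.3 CPM), and HLA-DRA, an MHC class II chain (chromosome 6, 823 ± 15.2 CPM). SEL1L3 (618 ± 2.86 CPM) and LRAT, a retinol acyltransferase gene (539 ± 18.9 CPM, 0 counts in rat), followed. In rat they were led by GLDN, which encodes gliomedin of the node of Ranvier (chromosome 15, 51341629 to 51408013), at 1285 ± 27.7 CPM with 3, 1 and 2 counts in the human libraries. EEF1G (620 ± 30.1 CPM), NME2 (409 ± 16.0 CPM), CD48 (398 ± 7.11 CPM), ENTPD2 (304 ± 42.7 CPM) and LUC7L2 (240 ± 36.9 CPM) followed. In human, another annotated gene covers 99.9% of the exonic bases of EEF1G, 29.8% of CD48, 23.8% of LUC7L2 and 22.9% of NME2. For GLDN and ENTPD2 the share is 0%. Ribosomal protein genes, which every cell expresses, also showed very low counts in rat, RPS9, RPS19 and RPLP2 being at 0.0690, 0.142 and 0.225 CPM against 91.5, 169 and 273 CPM in human. A low count in one species is therefore reported as a count and not as absence of expression.

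Genes of the myelin sheath were divided between the species. Changes of list members are given as log2 fold changes, human over rat. CNP, a myelin-associated phosphodiesterase, EGR2, the transcription factor that drives myelination, and DHH were lower in human, with changes of -2.28, -3.22 and -3.54. PMP22, MBP and PMP2, which encode myelin proteins, were higher in human by 1.77, 2.66 and 1.33. Of 23 genes on the list, 9 were higher in human and 13 in rat (median -1.08), and the list did not pass the test against other genes (camera adjusted p = 0.136).

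**Figure D3:**
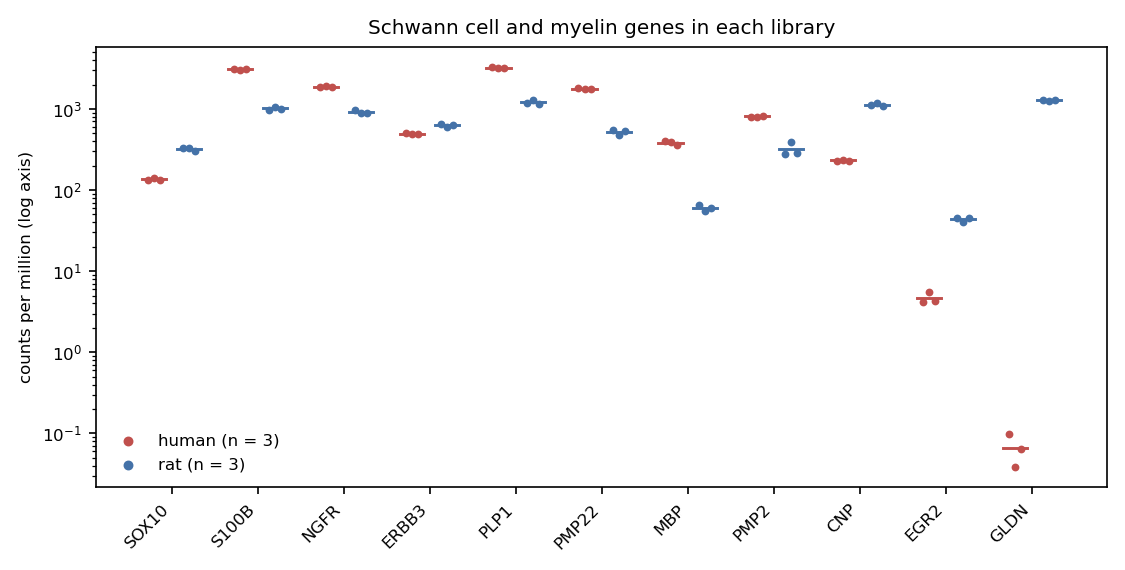
CPM (log axis) of Schwann cell and myelin genes in each of the 3 human and 3 rat libraries, with bars at the means. PMP22 lies at 1781 CPM in human and 521 CPM in rat, while CNP lies at 232 CPM in human and 1129 CPM in rat.

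Genes of immature and repair Schwann cells, of which 11 of 20 were higher in human and 9 in rat, also moved both ways (camera adjusted p = 0.859). JUN, a regulator of the repair state, was higher in human by 0.98, and the growth factor genes BDNF and GDNF by 4.37 and 2.45. SOX2 and CCND1 were lower in human (-1.37 and -2.09), and SHH was at 0.112 CPM in human and 29.8 CPM in rat. Cell division genes went both ways, with 11 of 30 higher in human and 14 in rat (median -0.12, median absolute log2 fold change 0.70, adjusted p = 0.976). MKI67, a marker of cycling cells, was at 370 ± 24.2 CPM in human and 562 ± 52.8 CPM in rat (log2 fold change -0.61), whereas CCNB2, a mitotic cyclin, was higher in human by 3.26.

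Antigen presentation genes were higher in human as a list, with 11 of 17 higher in human and 5 in rat (median 1.63, camera adjusted p = 0.0232, adjusted p = 0.403 with an estimated correlation). CIITA, the master regulator of MHC class II, was at 121 CPM in human with 0 counts in rat, B2M was at 1927 against 621 CPM, and the immunoproteasome gene PSMB8 at 33.6 against 0.102 CPM. IFI30, a lysosomal thiol reductase gene, went the other way, at 0.0215 CPM in human and 20.5 CPM in rat. Interferon response genes were not called as a list (13 of 20 higher in human, 5 in rat, adjusted p = 0.296). STAT2 and IFIT3 were higher in human by 2.47 and 8.01, while GBP2, a guanylate-binding GTPase, was at 43.0 ± 0.861 CPM in human and 4453 ± 353 CPM in rat. Among cytokine, chemokine and NF-kappaB target genes, 12 of 19 were higher in human and 7 in rat (adjusted p = 0.366). CXCL12 was higher in human by 5.05 and CXCL14 was lower (-5.99), and CCL2, whose row is paired with rat Ccl12, was at 40.8 CPM in human with 0 counts in rat.

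Fibroblast markers were higher in human as a list, with 13 of 17 higher in human and 4 in rat (median 5.01, camera adjusted p = 0.0251, adjusted p = 0.671 with an estimated correlation). COL1A2 was at 1899 ± 34.3 CPM in human and 58.9 ± 5.12 CPM in rat, whereas COL1A1, which encodes the partner chain of type I collagen, was at 258 ± 2.09 against 1654 ± 138 CPM. FAP was at 83.2 CPM in human and 0.104 CPM in rat, and LUM at 38.9 and 0.0364 CPM. Basement membrane genes were mostly higher in rat (13 of 18, with 5 higher in human), but the list was not called (median -0.87, adjusted p = 0.125). The laminin genes LAMC1 and LAMB1 were lower in human (-0.70 and -1.11), as was AGRN (-4.06).

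Oxidative phosphorylation genes were lower in human as a list, with 23 of 31 higher in rat and 5 in human (median -0.52, camera adjusted p = 0.0232, adjusted p = 0.639 with an estimated correlation). ATP5B and SDHA, which encode subunits of ATP synthase and of complex II, were lower in human (-1.69 and -1.90), and NDUFS1 of complex I was higher by 0.73. Glycolysis genes were not called (12 of 19 higher in human, 7 in rat, median 1.08, adjusted p = 0.125), with PKM and LDHB higher in human by 4.85 and 2.71. Cholesterol synthesis genes were not called (7 of 24 higher in human, 14 in rat, median -0.81, adjusted p = 0.0519, adjusted p = 0.671 with an estimated correlation). The adjusted p was 0.0370 without rat library 3 and 0.0417 with upper-quartile scaling, but 0.115 without rat library 2 and 0.165 without genes that share human exons or have a named pseudogene. HMGCS1, which makes the precursor of mevalonate, was at 139 CPM in human and 1140 CPM in rat. Fatty acid synthesis genes were not called (8 of 15 higher in human, 4 in rat, adjusted p = 0.673), with SCD higher in human by 2.50 and ACLY lower (-1.86).

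Ribosomal protein genes, included as a technical check, were called higher in human as a list (24 of 44 higher in human, 18 in rat, median 0.61, camera adjusted p = 0.0232, adjusted p = 0.403 with an estimated correlation). Their log2 fold changes ran from -5.10 for RPL7 to 10.44 for RPS9. Antigen presentation and oxidative phosphorylation had the same camera adjusted p of 0.0232. List calls at this level may therefore also come from how reads were counted in each species. Housekeeping genes were not called (5 of 17 higher in human, 10 in rat, adjusted p = 0.976). ACTB was at 2023 CPM in human and 1855 CPM in rat and was not called, while PPIA was higher in human by 3.33. Immediate-early genes were not called either (2 of 13 higher in human, 9 in rat, adjusted p = 0.125), with FOS and KLF4 lower in human (-1.46 and -4.33).

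Genes of cyclic AMP signalling (17 of 28 higher in human, 11 in rat, adjusted p = 0.976) and growth factor receptors (14 of 25 and 10, adjusted p = 0.853) were not called as lists. GNAS, the stimulatory G protein gene, was at 239 CPM in human and 1.53 CPM in rat, and the adenylyl cyclase gene ADCY5 at 0.116 and 108 CPM. GFRA2 was higher in human by 3.18, and EGFR was at 10.8 CPM in human and 0.0330 CPM in rat. The p53 target and senescence list (9 of 18 higher in human, 8 in rat, adjusted p = 0.976) included CCNG1, lower in human (-2.30), and ZMAT3, higher by 2.01. Its median of 0.07 became -0.13 with scaling by housekeeping genes. Melanocyte (3 of 6 higher in human, 2 in rat), mural cell (5 of 8 and 3), neuron (3 of 8 and 5), endothelial (4 of 6 and 1), perineurial (3 of 6 and 2) and leukocyte markers (2 of 5 and 2) gave adjusted p of 0.956, 0.481, 0.443, 0.976, 0.956 and 0.976. CSPG4 and NOTCH3 of the mural list were at 52.4 and 44.4 CPM in human and 0.159 and 0.213 CPM in rat, and PDGFRB was lower in human (-1.17). DCT and MITF of the melanocyte list were at 13.7 and 11.0 CPM in human, and TEK of the endothelial list was at 7.64 CPM in human and 45.5 CPM in rat.

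**Figure D4:**
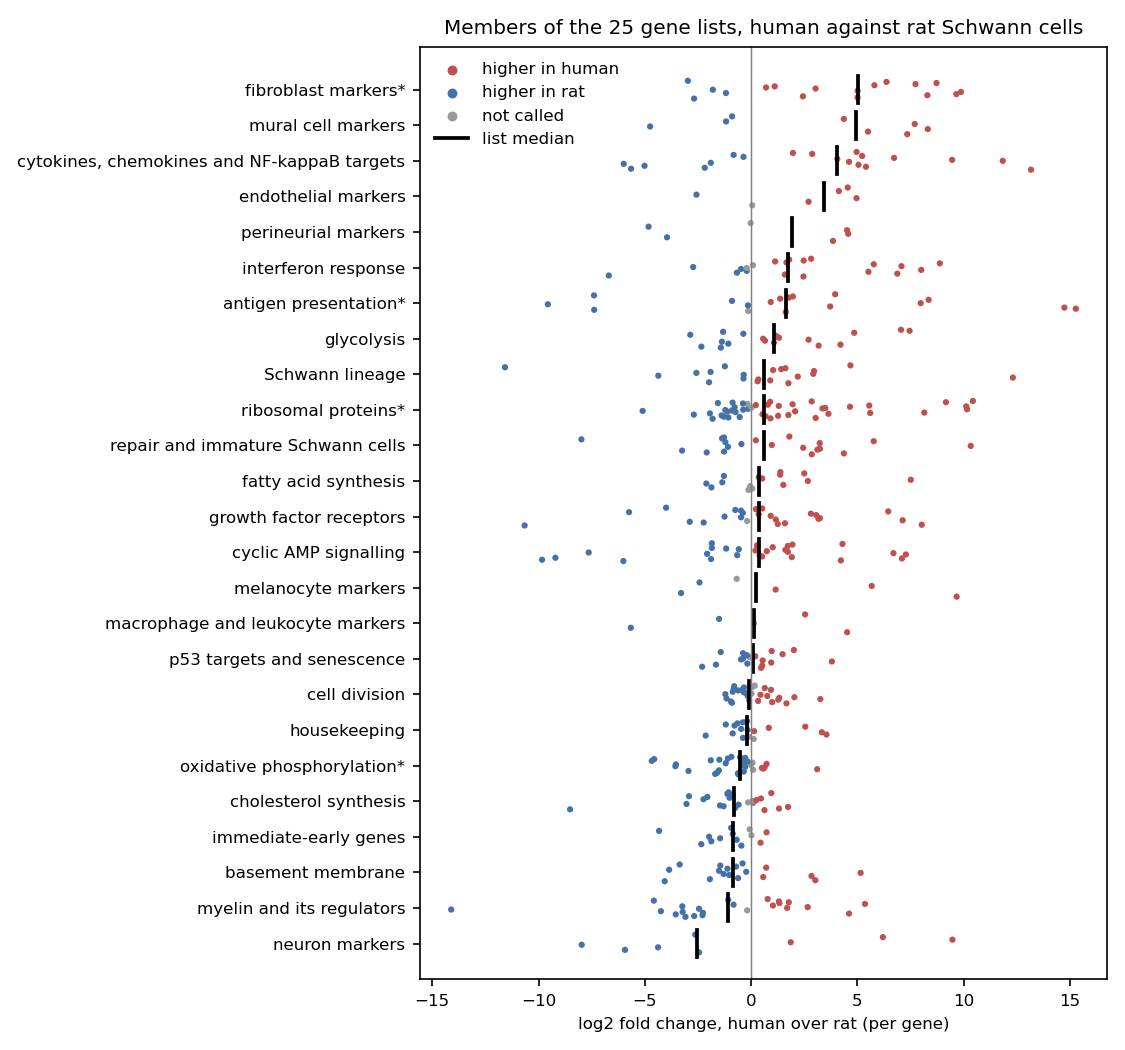
Fitted log2 fold change, human over rat, of each tested member of the 25 gene lists, with black bars at list medians and an asterisk at lists called by camera. Points of genes with no count in one species depend on the prior count, and the called medians are 5.01 (fibroblast markers), 1.63 (antigen presentation), 0.61 (ribosomal proteins) and -0.52 (oxidative phosphorylation). With an estimated correlation 0 of these lists were called.

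Counts adjusted over the list alone equalled those over all genes for every list except interferon response, where 4 genes rather than 5 were higher in rat. The median was positive and the camera direction was towards rat for the perineurial, endothelial, leukocyte, p53 and cyclic AMP lists, the last of which also had a mean of -0.03, and with housekeeping scaling the endothelial direction was towards human. For cell division and housekeeping genes the median was negative and the mean positive, at 0.15 and 0.19. Restricted to genes with at least 10 counts in each library, none of the 4 list calls held (camera adjusted p = 0.0870 for antigen presentation, oxidative phosphorylation and ribosomal proteins, and 0.453 for fibroblast markers, with 0 lists called). Without rat library 2, antigen presentation and fibroblast markers (adjusted p = 0.115 each) and ribosomal proteins (0.506) were not called, and without genes that share human exons or have a named pseudogene, an alternative chosen after seeing the data, oxidative phosphorylation was not (0.377).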

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

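All of these alternatives were fixed before the data were examined, except leaving out genes with shared human exons or named pseudogenes, which was chosen after the result was seen. Counts of genes that differed stayed within 1.5 times of 11287 under RLE, upper-quartile and housekeeping scaling, DESeq2, limma-voom and both count filters. The larger direction changed from human (5752 against 5535 in rat) to rat with upper-quartile scaling (5526 and 5818), housekeeping scaling (5165 and 6050) and at least 10 counts in each library (4566 and 4633), and at 2-fold with housekeeping scaling (3512 and 3744). A test against a 2-fold change passed 6604 genes (3609 higher in human, 2995 in rat), by construction of a stricter null. List calls were less stable: 0 lists (0 higher in human, 0 in rat) with at least 10 counts in each library, where fewer genes are compared, and 0 (0 and 0) with an estimated correlation. At an unadjusted p below 0.05, camera gave 7 lists and 2 lists under these settings. There were 24 (17 and 7) with fry, which tests another null, and 2 (0 in rat) without genes with shared exons or pseudogenes, where the ribosomal list had too few members for a value. Leaving out 1 library gave 11140 to 11652 genes (5678 to 5981 higher in human, 5459 to 5671 in rat), 7181 to 7295 genes at 2-fold (3830 to 3963 and 3321 to 3351), and 1 to 5 lists (0 to 3 and 1 to 2). The 1 list and the 0 higher in human came without rat library 2, and the 2 higher in rat came without rat library 3. The Spearman correlation between species was 0.689, with 0.692 to 0.698 when 1 library was left out and 0.669 over genes with at least 10 counts in each library. The coefficient of variation ran from 1.71% to 2.74% in human and from 2.64% (without rat library 2) to 8.94% in rat. MDM2 reversed, from 0.20 to -0.0018 (adjusted p = 0.984), with housekeeping scaling, which moved all genes by a median of -0.19, about the size of the MDM2 change, and it was not called with upper-quartile scaling (0.0556). CDH19 lost its call with housekeeping scaling (adjusted p = 0.457), with no filter (0.164) and without genes with shared exons or pseudogenes (0.0584), and PRKAR1A lost its call with housekeeping scaling (0.180). Calls were gained by CENPE, CALR and KLF6 with upper-quartile and housekeeping scaling, by SLC2A1 with housekeeping scaling, by CENPE, CALR and ACTB without rat library 1, and by CALR without rat library 3. The changes under these 2 scalings were about the size of the shift of all genes, a median of -0.091 with upper-quartile scaling. With housekeeping scaling CDH19 went from 0.31 to 0.10 and KLF6 from -0.07 to -0.26. With upper-quartile scaling CENPE went from -0.15 to -0.23. The cause was not tested for the changes under other settings. The replicate numbers did not pair the libraries: deviations of same-numbered libraries had correlations of 0.000326, -0.0217 and -0.0250. With the replicate block 11224 genes differed and 4 lists were called. The length correction was not run, since no rat exon lengths were used here. Genes with 0 to 3 counts in a species lie at the limit that depth allows.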

Other observations

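The gene families below and the tests of ubiquitous genes, leukocyte markers, class II loci and fibroblast markers were chosen after the result was seen, while the exon overlap tests and the splits of the libraries were planned. The p-values of the families are therefore descriptive. Their adjustment over 17 families included the MHC class II pathway, which was put together for its pattern and lowers the other adjusted values. Family values just below 0.05 are therefore not taken as calls. Of 33 collagen genes, 22 were higher in human and 9 in rat (median log2 fold change 3.02, camera adjusted p = 0.00178 over 17 families, adjusted p = 0.291 with an estimated correlation). COL11A1, a fibrillar collagen gene, was at 2343 ± 29.9 CPM in human and 37.7 ± 1.46 CPM in rat, and the type VI collagen genes COL6A1, COL6A2 and COL6A3 were higher in human by 4.96, 6.02 and 3.77. COL5A1, COL16A1 and COL18A1 were higher in rat (log2 fold changes -1.59, -2.82 and -1.94). FN1, which encodes fibronectin, was the most abundant gene in human at 9442 ± 85.2 CPM, against 97.9 ± 6.36 CPM in rat. In rat the most abundant gene was VIM, the intermediate filament vimentin, at 11498 ± 647 CPM, against 5138 ± 53.9 CPM in human. Guanylate-binding protein genes were lower in human in 5 of 6 cases (median -6.56, adjusted p = 0.00178, adjusted p = 0.339 with an estimated correlation), GBP7 having 0 to 2 counts per human library and 204 CPM in rat. GBP1 went the other way, at 76.7 CPM in human and 0.0516 CPM in rat. The row of GBP6, among the 5 lower in human, is paired with rat Mpa2l. Since the pairing rule is not given, differences within this family may depend on it.

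Of 24 HOX genes, which record position along the body axis, 19 were higher in human (HOXA7, whose row is paired with rat Hoxa9, among them) and 3 in rat, or 18 and 4 with housekeeping scaling, and the family was not called (adjusted p = 0.154). HOXB7 and HOXC9 were the most abundant in human, at 27.4 and 22.2 CPM against 9.51 and 5.20 CPM in rat. Fibroblast growth factor genes were higher in human in 6 of 7 cases (adjusted p = 0.0322, adjusted p = 0.291 with an estimated correlation), FGF5 being at 132 CPM against 15.2 CPM. IGF-binding protein genes were higher in 4 of 6 (adjusted p = 0.0447, adjusted p = 0.339 with an estimated correlation), IGFBP5 being at 6931 ± 133 CPM in human and 466 ± 39.3 CPM in rat.

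The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 11287 genes, 7135 genes at 2-fold and 4 lists, and the highest of the other splits gave 0, 0 and 1, with 0 genes at an unadjusted edgeR p below 0.05. For each of these counts 1 split, the real one, was as large. Every other split placed both species in each group, so the species difference became spread within groups. The low counts of those splits therefore say nothing about chance.

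Genes almost uncounted in one species raise the question whether reads were lost in counting. Among 53 annotated genes at 10 CPM or more in rat and nearly uncounted in human, 11 (20.8%, exact 95% interval 10.8 to 34.1) share at least 50% of their exonic bases with another human gene, against 130 of 7580 genes counted in all libraries (1.72%). The odds ratio was 15.0 (95% interval 7.56 to 29.8, Fisher's exact p = 2.27e-09). Shared exons may therefore account for some of these genes, such as EEF1G. The interval of 10.8 to 34.1% lies below 50%, so most of these genes do not reach this limit of sharing. Whether smaller overlaps also cost reads was not tested. NME2 and LUC7L2, with 22.9% and 23.8% shared, had 0 counts in human, but they were chosen for low human counts. NGFR and LDHB, with 27.1% and 33.4% shared, were at 1883 and 646 CPM in human. Shared exons therefore cannot be excluded as the cause for genes with an overlap below the limit. GLDN and ENTPD2, also in this set, share 0% of their exonic bases in this annotation. In the other direction, 0 of 85 ubiquitous genes (0%, upper bound 4.25%) had at most 3 counts in each rat library, against 186 of 8155 other genes (2.28%), and since the bound lies above that share, loss of reads in rat cannot be told apart from low expression, for the set as a whole or for some of its genes. A looser limit of 1 CPM was set when its outcome was already known and is given as a value, not as a test. It finds 4 of the 85 (4.71%), namely RPL38, RPLP2, RPS19 and RPS9, against 446 of the others (5.47%). Every cell expresses ribosomal proteins, so the low rat counts of these 4 genes may reflect lost reads. None of the 4 had at most 3 counts in each rat library, so they lie outside the set. A difference in expression between the species stays open and untested.

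MHC class II genes were counted in human and nearly uncounted in rat, with all 7 tested members of the pathway higher in human, and no p-value is given since the family was put together for this pattern. HLA-DOA and HLA-DQB1 were at 209 and 185 CPM in human with 0 counts in rat. Leukocytes that express the listed markers are argued against in the human cultures, since 0 of 17 leukocyte markers reached 1% of the CD74 level (11.5 CPM) in any human library. For CD68, among these markers, another annotated gene covers 85.8% of the human exonic bases, so its human counts may be too low. Loss of reads in rat cannot be told apart from low expression. The chance that the CD74, CIITA and MHC loci were all lost was 7.66e-05 at the upper bound for ubiquitous genes, but this decides nothing, since the loci were chosen for their low rat counts and losses need not be independent. Another candidate explanation that stays open is expression of the class II pathway by the human cells themselves, and a pairing of genes that differs between the species was not tested.

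Fibroblast markers were higher in human as a list (camera adjusted p = 0.0251), a call that was lost with an estimated correlation (adjusted p = 0.671), without rat library 2 (0.115) and with at least 10 counts in each library (0.453). A larger share of fibroblasts in the human cultures is a candidate explanation. Of 11 markers at 10 CPM or more in either species, 8 were higher in human and 3 (COL1A1, FBLN2 and PCOLCE) were lower by at least 2-fold. More fibroblasts alone would not lower those 3, but Schwann cells can express them too, so a larger share of fibroblasts cannot be told apart from a difference in the genes each species' Schwann cells express.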
